A study of Mus musculus with 17 samples.

How the data were processed

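Total RNA of mouse liver was measured on 17 Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample and none pooled, in 4 groups: wild type with corn oil (n = 5), wild type with TCDD (n = 6), AHR knockout with corn oil (n = 3) and AHR knockout with TCDD (n = 3). Groups and replicate numbers were taken from the sample titles. The values analysed are the deposited log2 expression values, 1 per probe set and array, which the authors had corrected for background, normalized across arrays and summarised per probe set. The submitters' processing notes name affy 1.5.8, RMA and GCRMA, and which of the latter methods made these values is not given in the sources used here. The table was checked to hold a log2 scale, with values from 0.333 to 15.9 and array medians from 3.08 to 3.19. Normalization across arrays sets their distributions alike, so a change shared by most genes would not be seen, and the top of the scale compresses differences between the most abundant transcripts. Arrays have no read depth; their number limits the precision. Scan settings deposited for each array gave the scan day (3 days) and fluidics module (4), and nothing else was used from them.

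Of 45101 probe sets, 64 Affymetrix controls were left out and 45037 were tested, with no filter on level. By the array annotation 34945 name 1 gene, 932 several and 9160 none, and 34741 of those with 1 gene matched the gene table used here by Entrez ID. That table follows the mouse assembly GRCm38.p6 and was used only for names and for the order of genes along chromosomes; no coordinates are given. Each of 18194 genes was represented by the probe set with the highest mean over all 17 arrays among those naming that gene alone. The control probe sets entered only checks of RNA quality and of hybridisation.

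A linear model with a mean for each of the 4 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which pools the spread over groups (13 residual degrees of freedom) and moderates it over probe sets (prior degrees of freedom 1.00). The contrasts tested were TCDD against corn oil in wild type, TCDD against corn oil in knockout, knockout against wild type with corn oil, and the difference of the TCDD effects (knockout minus wild type). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided, and a gene is said to have risen or fallen where its representative probe set was called. Errors of differences are standard errors of the model, and errors of group levels are standard deviations.

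In addition, 39 gene lists on AHR targets, foreign compound metabolism, lipid, sugar, amino acid and iron metabolism, hormone, clock, stress, inflammation and growth pathways and markers of liver and other cell types were tested with limma's camera on 1 probe set per gene. Camera compares a list with all other genes; its inter-gene correlation was preset at 0.01 and then estimated from the data, with adjustment over the 39 lists of a contrast. Counts of members are given over all probe sets and adjusted over the list alone. The lists, contrasts, tests, the rule for named genes and most alternatives were fixed before the data were examined. That rule named 8 receptor-related genes in every comparison, the 8 largest rises and 8 largest falls for TCDD in wild type and for genotype among called genes whose arrays did not overlap between groups, the 4 largest each way for the other contrasts (without that condition for the difference of effects), and up to 3 called members with the largest difference in each list described. A list was described where camera passed with the preset correlation or at least 25 percent of its measured members were called; the others are given as counts, and genes without a symbol or named only as sequence clones were counted and not named.

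Genotype calls near Ahr were compared with those elsewhere by a two-sided Fisher's exact test on the 100 nearest measured genes on each side. The correlation across genes between the TCDD and genotype effects, which share their control arrays, was set beside 100 simulations of unchanged groups and 20 divisions of the controls.

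The code was tested on simulated data of 45037 probe sets with the same group sizes, in which 100 probe sets were changed by 1 and 100 by 2 on the log2 scale. These were drawn from the probe sets above the median level, and the noise was independent and normal with no scan day effect. It recovered 87 and 98 of them for TCDD in wild type, 80 and 97 for TCDD in knockout, 81 and 97 for genotype and 68 and 93 for the difference of effects, with 11, 6, 7 and 7 false calls. Camera found the 1 shifted list and also called 2 other lists, with either correlation. Some lists share genes, so a list other than the shifted one may hold shifted genes. These 2 calls therefore do not measure how often camera calls an unchanged list.

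Alternatives changed 1 choice at a time: quantile normalization, centring each array on the median of its probe sets above the median level, testing only probe sets above the median level, a trended and robust prior, array weights, replicate number or scan day as a block, 1 probe set per gene, only the groups compared, an adjusted p under 0.01, a log2 difference of at least 1, and leaving out each array in turn. Fits within scan day 1 and scan day 2, the scan day block without the array of doubted RNA, and list tests without that array, without knockout TCDD replicate 1, with the replicate block and with median centring were added after seeing the data. Where such a fit left 1 array in a group, that array was assumed to vary like those of the other groups. Every array was kept in the values reported unless stated.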

Results

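Liver messenger RNA was measured on 17 Affymetrix Mouse Genome 430 2.0 arrays, each of which reads 45037 gene probe sets. The male mice carried or lacked the aryl hydrocarbon receptor (AHR), a transcription factor that binds dioxins, and were given corn oil or the dioxin TCDD at 1000 µg/kg by gavage 19 h before the liver was taken. The groups held 5 arrays of wild type mice given corn oil, 6 of wild type mice given TCDD, 3 of knockout mice given corn oil and 3 of knockout mice given TCDD. The knockout mice were 10 weeks old and came from a commercial breeder, whereas the wild type mice were 15 weeks old and bred at another site, so age and source went with genotype. Replicates are numbered in the labels without a statement that each array held RNA of a different mouse, so p-values measure the spread between these samples, which may be technical in part. The number of arrays limits the precision.

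Correlations between pairs of arrays ran from 0.982 to 0.998 across probe sets, and no pair was so alike as to be 1 sample deposited more than 1 time (lowest SD of the difference between 2 arrays, 0.180 on the log2 scale). Replicate 6 of the wild type TCDD group stood apart. Its residual SD was 0.319 against 0.124 to 0.173 on the other 16 arrays, and the gap between its 3′ and 5′ control probe sets was 1.98 for Gapdh (others -0.165 to -0.0112) and 1.75 for Actb (others 1.01 to 1.30). The arrays were scanned on 3 days. Day 1 held no knockout array with TCDD, and day 3 held only replicate 3 of the knockout TCDD group and replicate 5 of the wild type corn oil group.

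**Figure D1:**
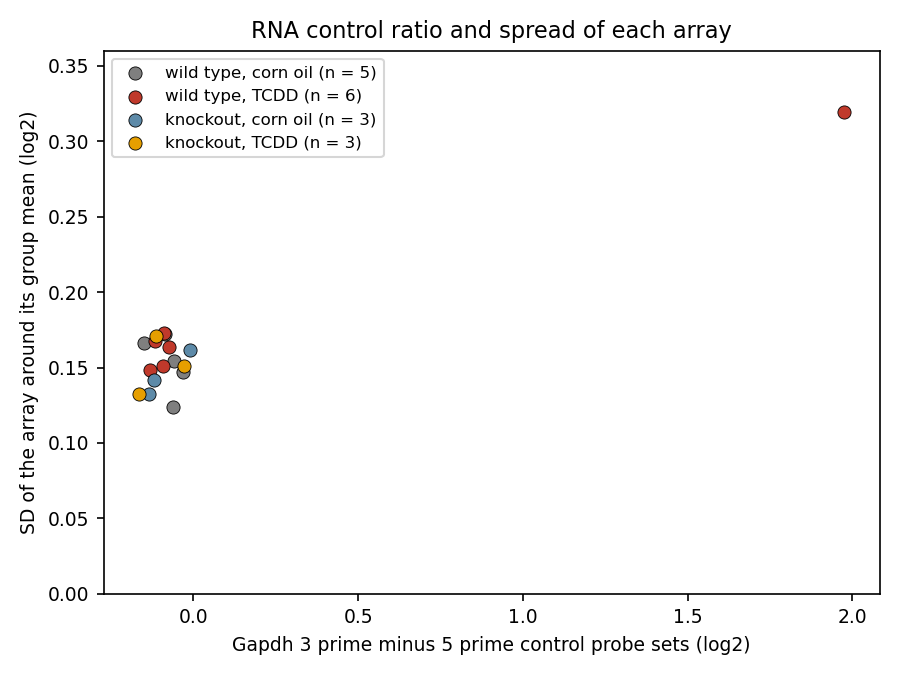
Each point is 1 of the 17 arrays: the horizontal axis gives the difference between the 3′ and 5′ control probe sets of Gapdh and the vertical axis the SD of the residuals over all probe sets, both on the log2 scale. Replicate 6 of the wild type TCDD group lies at 1.98 and 0.319, away from the other 16 arrays.

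The probe set for Ahr itself read 9.89 ± 0.38 (SD, n = 5) in wild type livers given corn oil and 9.50 ± 0.21 (n = 3) in knockout livers given corn oil. The difference was -0.39 ± 0.23 on the log2 scale (SE, adjusted p = 0.820). Where this probe set lies relative to the targeted part of the gene is not given in the sources used here, so its level does not report on the genotype. With TCDD the level of Ahr differed by 0.12 ± 0.19 in wild type and by -0.05 ± 0.25 in knockout livers. Arnt, the dimerisation partner of the receptor, did not pass the test over all probe sets in any comparison either, with differences of -0.11 ± 0.05 for TCDD in wild type, -0.31 ± 0.07 for TCDD in knockout and -0.11 ± 0.06 for genotype.

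The first comparison asked which transcripts the dose changed in livers with the receptor. The largest rise was that of Cyp1a1, a cytochrome P450 that oxidises aromatic hydrocarbons, from 5.95 ± 0.71 (SD, n = 5) to 15.20 ± 0.06 (n = 6), or at least 611-fold, as the dosed level is near the top of the scale. Cyp1b1, a related cytochrome, rose at least 67.8-fold from 3.41 to 9.49, and Tiparp, an ADP-ribosyltransferase, rose 54.8-fold from 4.72 to 10.50. The thyroxine-binding globulin gene Serpina7 had the largest fall, at least 30.1-fold from 8.64 ± 0.77 to 3.72 ± 0.34. The low levels of Cyp1b1 and Serpina7 lay near the array medians (3.08 to 3.19), where signal over background is small, so these folds are lower bounds. Transcripts of the hepcidin genes fell as well (SE, log2). That of Hamp, the gene of the hormone that limits iron uptake, fell by 1.68 ± 0.31, and that of Hamp2 fell by 2.54 ± 0.39.

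The other rises among the 8 largest of genes whose dosed arrays all lay above all control arrays were those of Pcp4l1 (6.28 ± 0.14, log2 difference ± SE), the alpha-tubulin Tuba8 (4.90 ± 0.16), the flavin monooxygenase Fmo2 (4.59 ± 0.13), the phosphomannomutase Pmm1 (4.43 ± 0.11) and the quinone reductase Nqo1 (4.33 ± 0.24). The corn oil levels of Pcp4l1 (2.11), Fmo2 (3.86), Pmm1 (3.57) and Nqo1 (3.15) were also near or below the array medians, so their differences are lower bounds too. Adjusted p for these 8 genes ran from 3.12e-12 (Pcp4l1) to 5.58e-05 (Cyp1a1). Cyp1a2 rose by at least 2.33 ± 0.25, or 5.03-fold, from a level of 13.31 ± 0.06 to 15.64 ± 0.05, near the highest value of any array (15.9), where differences are compressed. Ahrr, which encodes a repressor of the receptor, rose by 3.07 ± 0.31 from 2.41, a level below the median of every array (3.08 to 3.19). Falls with no overlap between the groups included thymidine kinase Tk1 (-1.92 ± 0.14), the retinol dehydrogenase Rdh9 (-1.81 ± 0.19), the cAMP phosphodiesterase Pde4b (-1.69 ± 0.38), the gluconeogenic enzyme Pck1 (-1.68 ± 0.28) and the actin regulator Carmil1 (-1.53 ± 0.27). The call for Pde4b ended without replicate 1 of the wild type corn oil group, where its difference was -1.39.

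**Figure D2:**
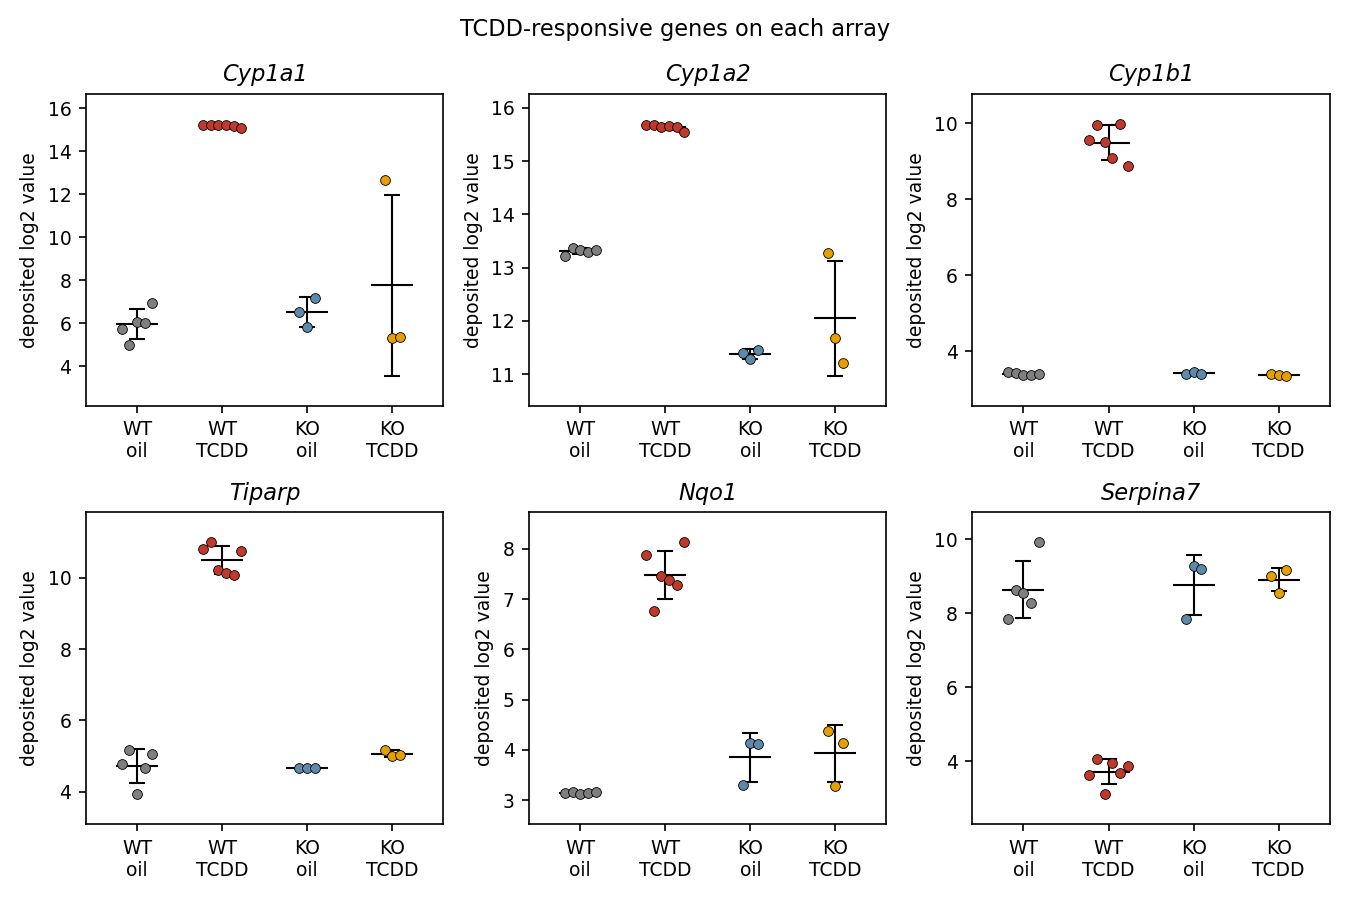
Dots give the log2 level of 6 genes on each of the 17 arrays in the 4 groups, bars the group means and error bars the SD. Cyp1a1, Cyp1a2, Cyp1b1, Tiparp and Nqo1 rose and Serpina7 fell with TCDD in wild type livers, and in the knockout TCDD group replicate 1 alone has a high level of Cyp1a1 (12.64).

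In the AHR gene battery, the set of known receptor targets, 9 of 10 measured genes rose, and the same number when adjusted over the list alone. The median log2 difference was 2.73 (camera adjusted p = 2.86e-24, and adjusted p = 1.35e-05 with an estimated correlation). Of 26 genes of the antioxidant response governed by NRF2, 15 rose (17 rose and 1 fell adjusted over the list alone), among them Nqo1, the carbonyl reductase Cbr3 (3.76 ± 0.24) and the glutathione transferase Gstm3 (2.10 ± 0.16). The NRF2 list had a median of 0.55 (adjusted p = 6.10e-17, and 0.00170 with an estimated correlation). Of 43 flavin monooxygenases and conjugating enzymes, 12 rose and 3 fell (13 and 6 adjusted over the list alone), with Ugdh, which makes UDP-glucuronate, up by 1.59 ± 0.08. That list had adjusted p = 0.00360, and adjusted p = 0.143 with an estimated correlation. Among 35 cytochromes of CYP families 2 to 4, 3 rose and 9 fell (4 and 13 adjusted over the list alone), with falls of Cyp3a25 (-0.79 ± 0.16), Cyp3a13 (-0.78 ± 0.11) and Cyp2u1 (-0.76 ± 0.14). The median of this list was -0.08 (adjusted p = 0.000141, and 0.143 with an estimated correlation).

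Of 28 genes of fatty acid and triglyceride synthesis, 3 rose and 5 fell (3 and 10 adjusted over the list alone), with a median of -0.29 and adjusted p = 4.06e-06, or adjusted p = 0.108 with an estimated correlation. Srebf1, a transcription factor of lipid synthesis, fell by 1.25 ± 0.21, the desaturase Fads2 differed by -1.04 ± 0.26, and the fatty acid transporter Cd36 rose by 1.09 ± 0.19. Of 28 glucose and glycogen genes, 3 rose and 3 fell (3 and 7 adjusted over the list alone; median -0.21, adjusted p = 0.00220, and 0.169 with an estimated correlation). Pck1 and the pyruvate kinase Pklr (-1.19 ± 0.16) fell, and Gckr, the regulator of glucokinase, rose by 0.77 ± 0.10. Of 37 genes of amino acid and urea cycle metabolism, 4 rose and 11 fell (9 and 19 adjusted over the list alone; median -0.26, adjusted p = 2.16e-05, and 0.234 with an estimated correlation), with Nags, which makes the activator of the urea cycle, up by 1.19 ± 0.09, Kynu down (-0.68 ± 0.09) and the histidine-degrading enzyme Amdhd1 at -0.75 ± 0.18. Of 28 bile acid genes, 2 rose and 5 fell (6 and 9 adjusted over the list alone). The exporter Abcc3 rose by 0.84 ± 0.10 and the peroxisomal oxidase Acox2 by 0.70 ± 0.07, and the oxysterol hydroxylase Cyp39a1 stood at -0.84 ± 0.22. The bile acid list had a median of -0.12 and adjusted p = 0.0319, which became 0.237 without replicate 6 of the TCDD group and was 0.238 with an estimated correlation. Calls for Fads2, Cyp39a1 and Amdhd1 ended without any 1 of 14, 13 and 6 of the 17 arrays, over ranges of -1.13 to -0.76, -0.99 to -0.70 and -0.88 to -0.66.

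Of 39 acute phase and inflammation genes 9 fell (12 adjusted over the list alone; median -0.21, adjusted p = 1.95e-07, and 0.135 with an estimated correlation), including the metalloreductase Steap4 (-1.10 ± 0.11) and the lipopolysaccharide-binding protein gene Lbp (-0.94 ± 0.14). Saa4 stood at -0.68 ± 0.17, a call that ended without any 1 of 7 arrays (-0.74 to -0.58). Among 33 complement and coagulation genes 1 rose and 9 fell (1 and 13 adjusted over the list alone; median -0.08, adjusted p = 4.06e-06, and 0.143 with an estimated correlation), with Pros1 at -0.43 ± 0.06, C1s1 at -0.34 ± 0.06 and C8a at -0.35 ± 0.08. The C8a call ended without replicate 1 or 4 of the corn oil group (range over all arrays left out, -0.39 to -0.30) and after median centring. Of 30 genes of the unfolded protein and amino acid stress response 2 fell (9 adjusted over the list alone; median -0.33, adjusted p = 4.80e-08, and 0.143 with an estimated correlation). These were the stress sensors Ern1 (-0.69 ± 0.09) and Eif2ak3 (-0.81 ± 0.20, lost without any 1 of 9 arrays, -0.90 to -0.69). Haem and iron genes went both ways: 5 of 23 rose and 4 fell (6 and 5 adjusted over the list alone), with falls of Hamp2 and Hamp, and the transferrin receptor Tfrc stood at 1.31 ± 0.31, lost without any 1 of 5 arrays (1.06 to 1.54). The median of this list was 0.02 and its mean -0.08 (adjusted p = 0.860).

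Of 18 genes with male-biased expression in liver, 1 rose and 2 fell (1 and 5 adjusted over the list alone; median -0.40, adjusted p = 6.34e-05, and 0.147 with an estimated correlation), with falls of Cyp2u1 and Keg1 (-0.68 ± 0.12) and a difference of 0.16 ± 0.04 for Gstp1. Of 16 genes of the growth hormone and IGF axis, 1 rose and 3 fell (1 and 5 adjusted over the list alone; median -0.16, adjusted p = 0.00301, and 0.108 with an estimated correlation), with Ghr, the growth hormone receptor, at -0.44 ± 0.05, Igfals at -0.47 ± 0.10 and Fgfr4 at 0.33 ± 0.08. Among 19 clock genes 1 fell, also when adjusted over the list alone, namely Cry1 (-1.56 ± 0.41). The clock list had a median of -0.22 and adjusted p = 0.0369, which was 0.133 with scan day as a block, 0.232 without replicate 6, 0.0631 after quantile normalization and 0.170 with an estimated correlation. Calls for Cry1, Gstp1 and Fgfr4 ended without any 1 of 15, 13 and 11 arrays, over ranges of -1.80 to -1.25, 0.13 to 0.18 and 0.26 to 0.38, that for Gstp1 also after median centring and that for Cry1 after quantile normalization (adjusted p = 0.0562).

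Of 10 hepatocyte markers 3 fell (5 adjusted over the list alone; median -0.06, adjusted p = 0.00117, and 0.170 with an estimated correlation): Apoa1 by 0.14 ± 0.03, Ahsg by 0.10 ± 0.02 and Apoc3 by 0.09 ± 0.02. These 3 calls were lost after median centring, that for Ahsg also after quantile normalization (adjusted p = 0.195), and those for Ahsg and Apoc3 also without any 1 of 5 and 7 arrays (-0.11 to -0.09 and -0.10 to -0.08). The list call was lost after that centring (adjusted p = 0.0980) and without replicate 6 (0.0524). Of 14 endothelial markers 3 fell (4 adjusted over the list alone; median -0.15, adjusted p = 0.000343, and 0.143 with an estimated correlation), namely the lectin Clec4g (-0.55 ± 0.07) and the scavenger receptors Stab2 (-0.35 ± 0.05) and Stab1 (-0.35 ± 0.09, lost without any 1 of 8 arrays, -0.40 to -0.31, and after median centring). Among 13 stellate cell and fibroblast markers 1 fell (1 rose and 4 fell adjusted over the list alone), Rgs5 (-0.48 ± 0.09). That list had adjusted p = 0.0256, or 0.173 without replicate 6 and 0.415 with an estimated correlation. Over the 11 lists for cell types other than hepatocytes, 6 of 108 genes were called, against 14 at an unadjusted p under 0.05. Of all 18194 genes 1149 were called, a similar share.

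In all, 1882 probe sets passed (1146 higher, 736 lower), and 287 of them differed at least 2-fold. The balance of directions depended on the setting, with 1357 higher and 580 lower after median centring and 1148 and 1089 with array weights. By genes with 1 representative probe set each, 683 rose and 466 fell. Of the 39 lists, 18 are described above and the other 21 had at most 6 called members each. None of the 30 cell cycle genes measured was called by limma, against 5 at an unadjusted p under 0.05. With scan day as a block 1812 probe sets passed, 1619 of them the same ones, and without replicate 6 the count was 1866. Within scan day 1 (2 dosed arrays against 1) 456 probe sets passed (184 higher, 272 lower), 95 of them shared, and within scan day 2 (4 against 3) 564 passed (380 higher, 184 lower), 524 of them shared. A lone array in a within-day fit was assumed to vary like the arrays of the other groups. Of the 57 named calls 8 passed within day 1, 31 within day 2 and 51 with the block, and the 6 lost with the block were Cry1 (adjusted p = 0.0577), Eif2ak3 (0.0607), Saa4 (0.0642), Fads2 (0.0764), Gstp1 (0.102) and Cyp39a1 (0.108). The median of the AHR gene battery was 2.48 within day 1 and 2.90 within day 2, that of the NRF2 list was 0.62 and 0.45, and all 18 lists kept the sign of their median within both days. Some day 1 medians were near 0, at -0.012 for fatty acid, -0.018 for glucose, -0.023 for clock and -0.016 for stellate cell genes, and with the block 17 of 18 lists kept their sign, the haem and iron median turning to -0.021.

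**Figure D3:**
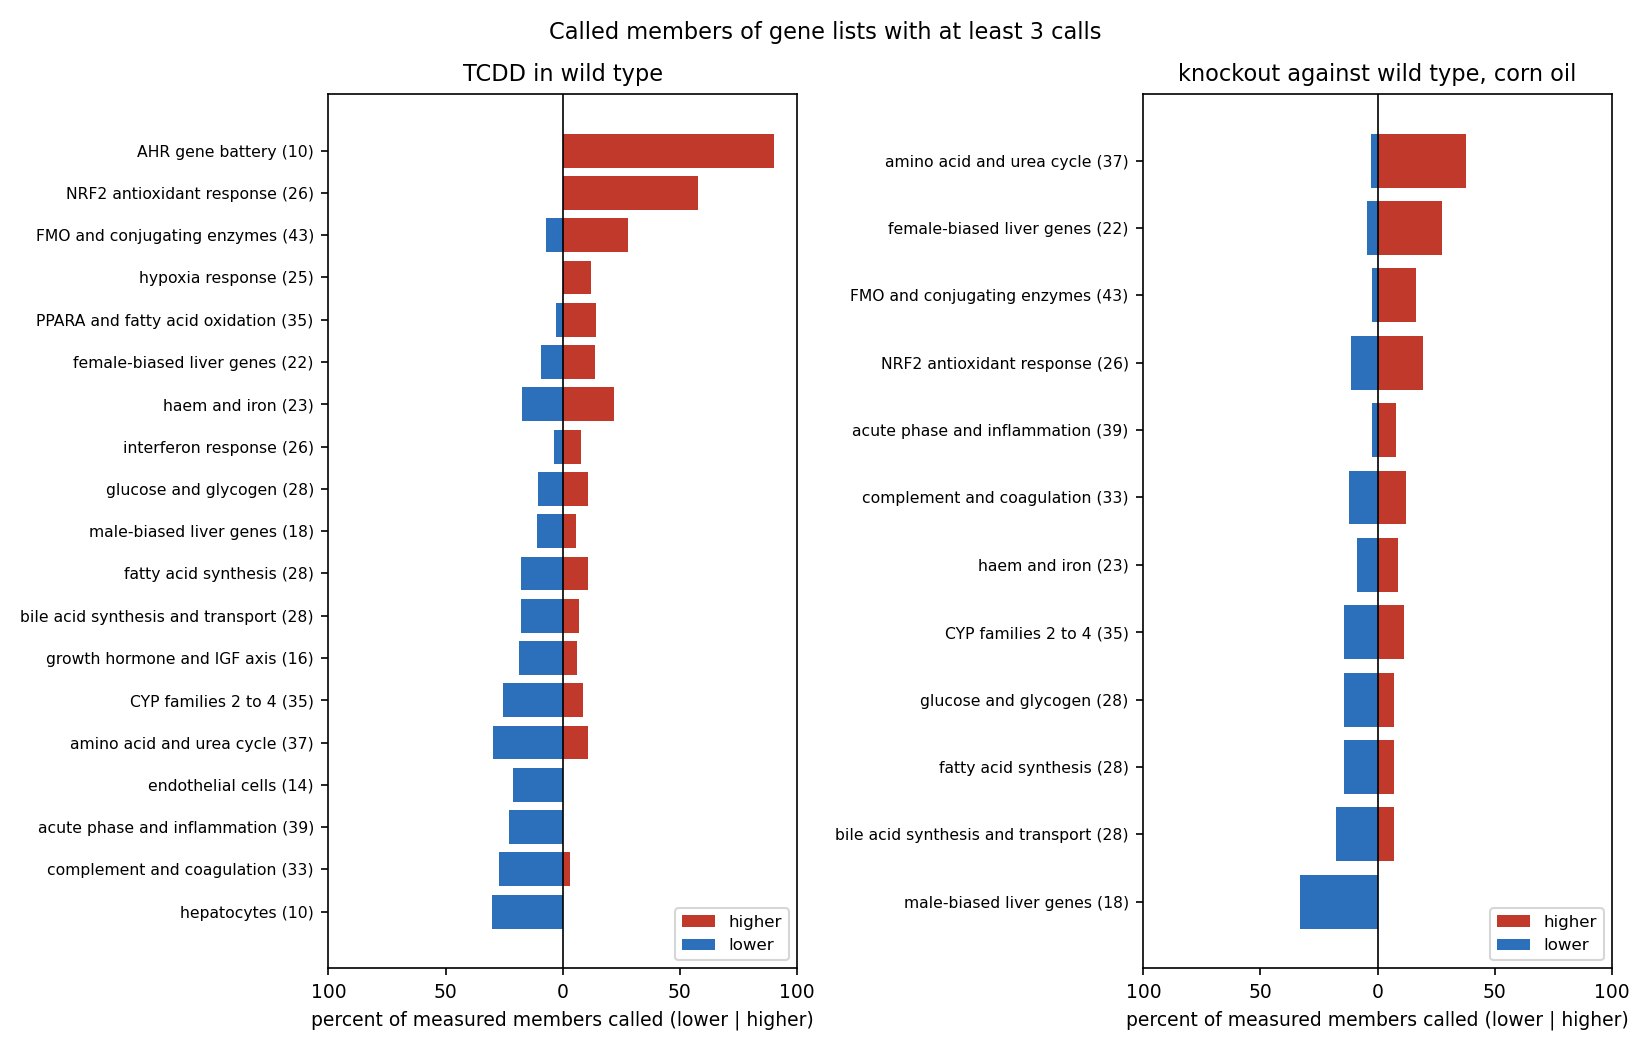
Bars give the percent of a list's measured genes called higher or lower (limma adjusted p under 0.05), for TCDD in wild type livers and for genotype in livers given corn oil, in lists with at least 3 calls. With TCDD the AHR gene battery (9 of 10) and the NRF2 list (15 of 26) have calls in the higher direction only, and the acute phase list (9 of 39) in the lower direction only.

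The second comparison asked which transcripts TCDD changed without the receptor. Serpina12, which encodes the secreted protease inhibitor vaspin, was at least 4.42-fold higher with TCDD, at 6.10 ± 0.09 (SD, n = 3) against 3.95 ± 0.45 (n = 3) in livers given corn oil, a level near background, with all 3 dosed arrays above all 3 others. Ptgfrn was higher by 0.23 ± 0.03 (SE), from 3.10 to 3.32, a level near the median of an array. None of the genes raised most in wild type livers passed here: the log2 difference was 1.26 ± 1.36 for Cyp1a1, 0.67 ± 0.34 for Cyp1a2, 0.40 ± 0.29 for Tiparp, 0.08 ± 0.33 for Nqo1, -0.01 ± 0.42 for Ahrr and -0.04 ± 0.22 for Cyp1b1. The Cyp1a1 difference rested on replicate 1, where the level was 12.64 against 5.32 and 5.34 on the other knockout TCDD arrays, and without that array it was -1.18. The Cyp1a2 difference rested on the same array and was 0.063 without it.

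Limma called 6 probe sets, all higher, against 1263 at an unadjusted p under 0.05. Besides Serpina12 and Ptgfrn these were probe sets of Vegfc (1.03), Jag1 (0.60), Mrpl47 (0.59) and Chd7 (0.20), which fall outside the rule for named genes and were chosen after their values were seen. In simulated data for this comparison, 80 of 100 probe sets changed by 1 on the log2 scale were recovered among 45037, and 97 of 100 changed by 2. The changed probe sets lay above the median level and the simulation held no scan day effect, so recovery in the real arrays may be lower. The calls depended on single arrays. Leaving out a knockout array gave 13 to 34 probe sets (13, 29 and 27 without corn oil replicates 1, 2 and 3, and 24, 34 and 25 without TCDD replicates 1, 2 and 3). Their directions varied, with 5 higher and 8 lower, 8 and 21, and 11 and 16 without the corn oil replicates, and 21 and 3, 33 and 1, and 23 and 2 without the TCDD replicates. Wild type arrays bear only on the shared estimate of the spread, and leaving 1 out gave 1 to 6 probe sets. The call for Serpina12 ended without any 1 of 8 arrays, over a range of 2.005 to 2.405, and that for Ptgfrn without any 1 of 6 (0.22 to 0.24) and after median centring (adjusted p = 0.919). With scan day as a block 1 probe set passed, none of them shared with the 6, and Serpina12 had a difference of 2.19 (adjusted p = 0.279) and Ptgfrn of 0.21 (0.362). Within scan day 2 (2 dosed arrays against 1, the lone array assumed to vary like the others) 255 passed, 47 higher and 208 lower, 2 of them shared.

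In the knockout limma called no gene of any list when adjusted over all probe sets, out of 763 genes in the 39 lists, of which 47 had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene was lower among the AHR signalling components (Arnt) and 1 in the growth hormone and IGF axis (Igfals). Camera with the preset correlation placed 7 lists apart from the other genes, and none with an estimated correlation. Male-biased liver genes had a median of 0.25 (adjusted p = 1.67e-05, and 0.374 with an estimated correlation), extracellular matrix genes of 0.10 (1.97e-05, and 0.374) and heat shock proteins of 0.13 (0.000305, and 0.374). Stellate cell markers had a median of 0.05 (0.00841, and 0.755), female-biased genes of -0.08 (0.0359, and 0.810) and genes of PPARA and fatty acid oxidation of -0.11 (0.0415, and 0.829). Genes of the mitochondrial respiratory chain had a median of 0.02 (0.00301, and 0.810), which turned to -0.00018 when arrays were centred on their medians (adjusted p = 0.0909). Quantile normalization ended the call for stellate cell markers (0.0834). Without replicate 1 of the knockout TCDD group the calls for PPARA (0.0857), the respiratory chain (0.0952) and stellate cells (0.119) were lost, without replicate 6 of the wild type TCDD group those for PPARA (0.330) and female-biased genes (0.101), and with the scan day block that for PPARA (0.331). Within scan day 2 the medians kept their sign for 6 of the 7 lists, and that of PPARA was 0.0029. The medians there were 0.049 for male-biased, -0.025 for female-biased, 0.099 for heat shock and 0.16 for extracellular matrix genes. They were 0.089 for the respiratory chain and 0.055 for stellate cell markers. The knockout corn oil arrays enter this contrast and the genotype contrast with opposite signs, so list results of the 2 are not independent.

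The third comparison asked which transcripts differed between the genotypes without the dose. In knockout livers given corn oil, the metallothioneins, which bind zinc and copper, were far higher: Mt1 read 13.31 ± 0.33 (SD, n = 3) against 6.90 ± 0.81 (n = 5) in wild type, or 85.5-fold, and Mt2 was 46.2-fold higher (5.53 on the log2 scale, and 5.14 to 6.14 without each array in turn). Serpina12 was at least 225-fold lower, at 3.95 ± 0.45 against 11.77 ± 0.26. The steroid enzyme Hsd3b5, a male-biased gene, was 9.20-fold lower, and the steroid hydroxylase Cyp17a1, a female-biased gene of mouse liver, was at least 30.4-fold higher, from a level of 3.26, near the median of an array. Of the receptor's own targets Cyp1a2 was 3.81-fold lower, at 11.38 ± 0.09 against 13.31 ± 0.06.

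**Figure D4:**
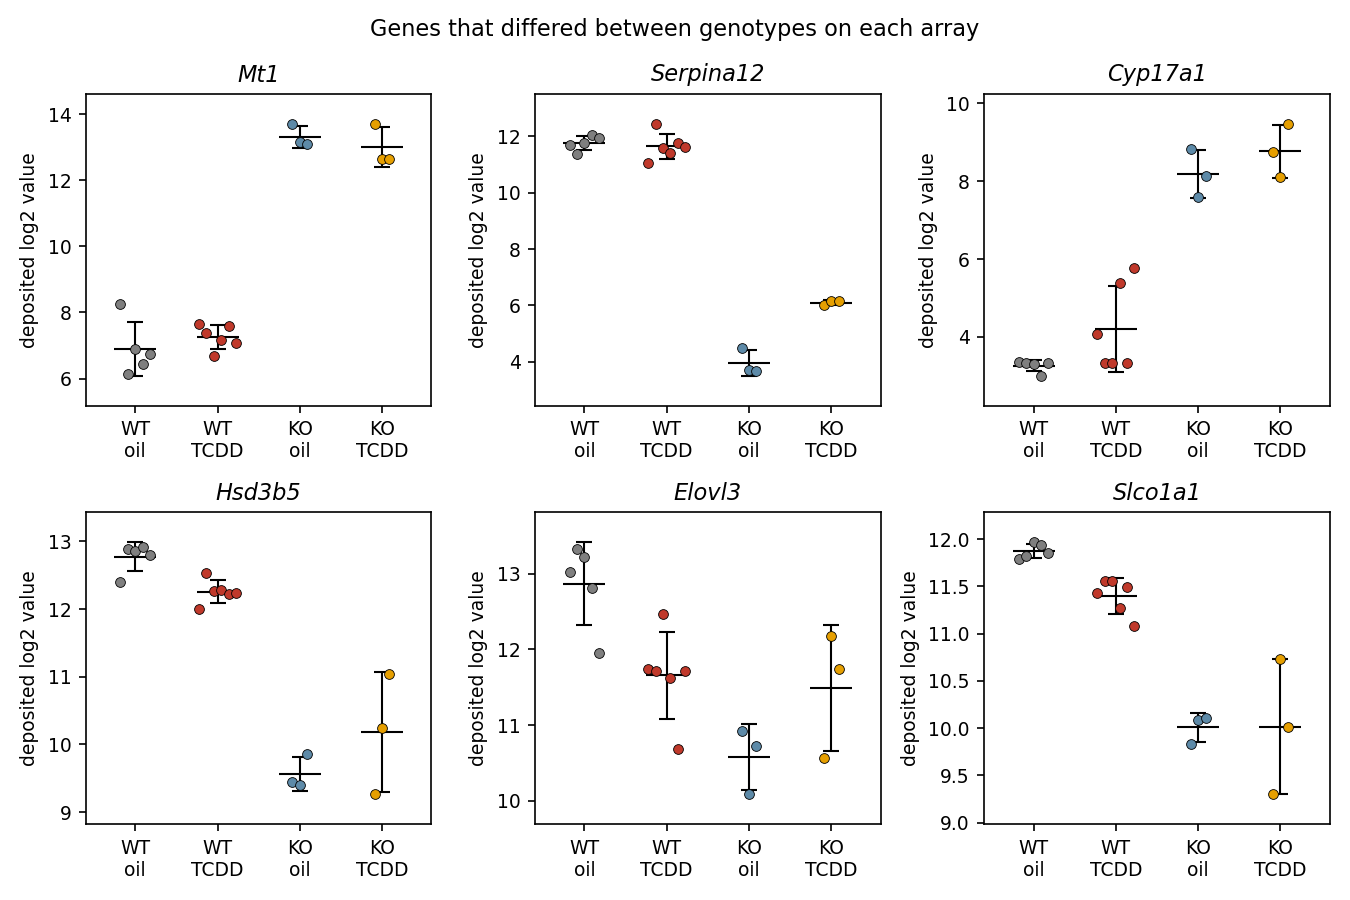
Dots give the log2 level of 6 genes on each of the 17 arrays in the 4 groups, bars the group means and error bars the SD. In livers given corn oil Mt1 and Cyp17a1 were higher and Serpina12, Hsd3b5, Elovl3 and Slco1a1 lower in the knockout than in the wild type.

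Further rises with no overlap between the 2 groups were those of the trefoil factor Tff3 (4.97 ± 0.38, log2 difference ± SE), Mmd2 (4.53 ± 0.24), the transcription factor gene Tcf24 (3.99 ± 0.22), the proton pump subunit Atp4a (3.86 ± 0.19) and the monocarboxylate transporter Slc16a5 (3.07 ± 0.38). Falls of this kind were those of Nxpe2 (-3.98 ± 0.29), the organic anion transporter Slc22a7 (-3.16 ± 0.27), the noncoding Hectd2os (-2.59 ± 0.41), Tsc22d1 (-2.58 ± 0.24), Rarres1 (-2.57 ± 0.38) and the methionine salvage enzyme Adi1 (-2.53 ± 0.29). Adjusted p was 1.47e-06 for Mt1, 0.000208 for Cyp17a1, 1.61e-09 for Serpina12, 2.16e-05 for Hsd3b5 and 0.00364 for Cyp1a2. Of the 10 measured genes of the AHR battery 1 other passed, Gsta2, which was higher (2.02 ± 0.29). Further receptor-related genes named in every comparison did not pass, with 0.71 ± 0.30 for Nqo1, 0.56 ± 1.21 for Cyp1a1, 0.01 ± 0.20 for Cyp1b1, 0.01 ± 0.38 for Ahrr and -0.05 ± 0.26 for Tiparp.

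Of 18 male-biased liver genes 6 were lower in the knockout (10 lower adjusted over the list alone), among them Hsd3b5, the fatty acid elongase Elovl3 (-2.29 ± 0.42) and the organic anion transporter Slco1a1 (-1.87 ± 0.22). The list's median was -0.79 (adjusted p = 1.49e-17, and 0.0178 with an estimated correlation, which was 0.0551 with scan day as a block). Within scan day 1 the median was -0.93 and within day 2 -0.66. Of 22 female-biased genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.46, adjusted p = 4.81e-08, and 0.296 with an estimated correlation), including Cyp17a1, Slc16a5 and Cyp2b10 (2.69 ± 0.36). The Elovl3 call ended without replicate 2 of the knockout corn oil group (-2.52 to -2.04 over all arrays left out).

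Among metabolic lists, 14 of 37 genes of amino acid and urea cycle metabolism were higher and 1 lower (22 and 1 adjusted over the list alone; median 0.34, adjusted p = 7.87e-14, and 0.159 with an estimated correlation). Asparagine synthetase Asns was higher by 2.36 ± 0.40 and glutamine synthetase Glul lower by 1.02 ± 0.08, and Agxt stood at 0.86 ± 0.17, a call that ended without knockout corn oil replicate 1 or 3 or wild type corn oil replicate 4 (0.77 to 0.97). Of 35 cytochromes of CYP families 2 to 4, 4 were higher and 5 lower (6 and 11 adjusted over the list alone), with Cyp2b10 and Cyp4a14 (2.12 ± 0.39) higher and Cyp2u1 (-1.16 ± 0.17) lower. The median of these cytochromes was -0.05 and their mean 0.05 (adjusted p = 0.00798 for a shift down, 0.0557 after median centring, and 0.511 with an estimated correlation). Of 28 bile acid genes 2 were higher and 5 lower (3 and 7 adjusted over the list alone), with Slco1a1 and Slco1b2 (-0.67 ± 0.11) lower and Slco1a4 at 2.60 ± 0.50. Their median was -0.06 and mean 0.02 (adjusted p = 0.0495 for a shift down, and 0.511 with an estimated correlation), and with scan day as a block the median turned to 0.0060 (adjusted p = 0.0762). That call was also lost after quantile normalization (0.118) and median centring (0.263). Calls ended without knockout corn oil replicate 2 for Cyp4a14 (1.79 to 2.32) and without replicate 2 or 3 of that group for Slco1a4 (2.40 to 2.97).

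Of 26 NRF2 genes 5 were higher and 3 lower (7 and 5 adjusted over the list alone; median 0.07, adjusted p = 0.870), including Gsta2 (2.02 ± 0.29), Gstm3 (1.37 ± 0.20) and haem oxygenase Hmox1 (1.08 ± 0.18). Of 39 acute phase genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.000699, and 0.511 with an estimated correlation), the 3 being Mt1, Mt2 and Itih3 (0.47 ± 0.07), and the median was -0.01 within scan day 1. Of 14 heat shock genes 2 were higher (4 adjusted over the list alone; median 0.32, adjusted p = 0.000283, and 0.296 with an estimated correlation), Hspb8 by 1.09 ± 0.10 and Hspd1 by 0.27 ± 0.06. Among 32 respiratory chain genes 1 was higher and 1 lower (3 and 1 adjusted over the list alone), Uqcrfs1 at 0.22 ± 0.05 and Ndufb3 at -0.39 ± 0.08. Among 10 hepatocyte markers 1 was higher (3 adjusted over the list alone), Ahsg by 0.15 ± 0.03. These last 2 lists had medians of 0.09 and 0.04 and adjusted p of 0.0386 and 0.0322, or 0.876 and 0.595 with an estimated correlation, and both calls were lost with scan day as a block (0.348 for each) and after median centring (0.177 and 0.191), that for the respiratory chain also after quantile normalization (0.156). Calls for Hspd1, Uqcrfs1, Ndufb3 and Ahsg ended without any 1 of 14, 13, 7 and 2 arrays (0.25 to 0.32, 0.19 to 0.25, -0.43 to -0.36 and 0.12 to 0.19), those of the first 3 also with the scan day block (adjusted p = 0.154, 0.0745 and 0.119) and those of Hspd1, Uqcrfs1 and Ahsg after median centring. Quantile normalization ended those of Hspd1 (0.173) and Uqcrfs1 (0.0542).

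The genotype comparison called 654 probe sets, 393 higher and 261 lower in the knockout, of which 172 differed at least 2-fold, and 255 genes were higher and 170 lower. The balance of directions depended on scaling: 60.1% were higher in the deposited values, 48.1% after quantile normalization and 47.8% after median centring. The other 29 lists had at most 8 called members each, and 4 of 108 markers of other cell types were called, beside 425 of all 18194 genes. With scan day as a block 514 probe sets passed, 453 of them the same ones. Within scan day 1 (2 knockout arrays against 1) 294 passed (100 higher, 194 lower), 21 of them shared, and within day 2 (1 against 3) 479 passed (363 higher, 116 lower), 132 of them shared, with a lone array in each. Of the 36 named calls 33 passed with the block, 1 within day 1 and 15 within day 2. Of the 10 lists, 6 kept the sign of their median within day 1 and 9 within day 2. Without replicate 1 of the knockout corn oil group the count fell to 404, and without replicate 6 of the wild type TCDD group it was 780. Age and source of the mice cannot be told apart from genotype in any of these values.

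Around the targeted gene, 9 of the 200 nearest measured genes (100 on each side of Ahr) were called by genotype, or 4.5%, against 416 of 17831 elsewhere (2.33%). The odds ratio was 1.97 (95% confidence interval 0.882 to 3.86, two-sided Fisher's exact p = 0.0562), which did not pass. It was 1.73 (exact p = 0.302) with 50 genes on each side and 1.40 (exact p = 0.273) with 200. The called neighbours were Adi1 (-2.53), Eipr1 (-0.80), Kidins220 (-0.55), Sntg2 (1.64), Itgb1bp1 (0.84), Sptssa (0.81), E2f6 (0.60), Cpsf3 (0.42) and Ywhaq (0.25). Of 14021 windows of this size along the chromosomes, 1002 (7.15%) held 9 or more calls.

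The title of the study sets genes that depend on dioxin against genes that depend on the receptor alone, and both effects can be set side by side across genes. The Pearson correlation across 18194 genes between the TCDD effect in wild type and the genotype effect in corn oil was 0.0585 (jackknife SE 0.0511), and Spearman's rho was 0.161. Genes are not independent replicates. Because the 5 wild type corn oil arrays enter both differences, unchanged groups set against the same controls gave a simulated median r of 0.453, and dividing these controls between the comparisons gave -0.0870 to 0.0356 over 20 divisions, with a median of -0.0196. The simulated groups held noise alone, and effects unrelated to each other would widen both differences and lower r. The simulated r of 0.453 therefore cannot be set directly against 0.0585. The covariance was 0.00486 against a simulated 0.00737. In all 148 genes were called in both, where independent lists would share 26.8. Of these, 46 were higher in both, 40 lower in both, 25 higher with TCDD and lower in the knockout, and 37 the reverse. With divided controls, at most 11 genes were called in both (median 5, against 0.850 for independent lists).

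The fourth comparison tested the difference between the TCDD effects, knockout minus wild type. Some named genes that rose with TCDD in wild type had smaller effects in the knockout. The difference was -6.28 ± 0.23 (SE, log2) for Pcp4l1, -6.12 ± 0.27 for Cyp1b1, -5.38 ± 0.36 for Tiparp, -4.90 ± 0.21 for Fmo2, -4.26 ± 0.41 for Nqo1 and -3.08 ± 0.52 for Ahrr. In the other direction the difference was 5.05 ± 0.58 for Serpina7, which read 8.78 with corn oil and 8.91 with TCDD in the knockout, 1.92 ± 0.24 for Tk1 and 1.75 ± 0.23 for Enho, the adropin gene. Serpina12 gave 2.27 ± 0.36. Cyp1a1 gave -8.00 ± 1.69 (adjusted p = 0.0347), a call lost without any 1 of 15 arrays (-10.43 to -6.77), with -10.43 without replicate 1 of the knockout TCDD group. Cyp1a2 gave -1.66 ± 0.42 and did not pass (adjusted p = 0.0935). It passed without replicate 1 of the knockout TCDD group (-2.27, adjusted p = 4.22e-07) and when only probe sets above the median level were tested (0.0426).

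In the AHR gene battery the effect was lower in the knockout for 7 of 10 genes (9 adjusted over the list alone; median -2.51, adjusted p = 1.10e-20, and 3.36e-05 with an estimated correlation). The same held for 12 of 26 NRF2 genes (15 adjusted over the list alone; median -0.55, adjusted p = 3.12e-11, and 0.0109 with an estimated correlation, which was 0.0928 with scan day as a block), with Cbr3 at -3.66 ± 0.40 and the sulfiredoxin gene Srxn1 at -1.83 ± 0.26. It held for 9 of 43 flavin monooxygenases and conjugating enzymes (2 higher and 11 lower adjusted over the list alone), with Gstm3 at -1.79 ± 0.28 and Sult5a1 at -1.82 ± 0.33, and that list's adjusted p of 0.0393 was 0.0597 without wild type TCDD replicate 6, 0.0680 without knockout TCDD replicate 1 and 0.274 with an estimated correlation. Of 22 female-biased genes 2 were lower (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.0320, 0.0597 without replicate 6 and 0.566 with an estimated correlation), including the acyl-CoA thioesterase Acot3 (-4.84 ± 0.84). The call for Sult5a1 ended without knockout corn oil replicate 1 (-2.03 to -1.61).

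Because the same wild type arrays enter this difference and the TCDD effect in wild type, list results of the 2 are not independent. Male-biased genes had a median of 0.42 with 1 called, Cyp2u1 at 1.19 ± 0.23 (4 adjusted over the list alone; adjusted p = 4.31e-08, and 0.0926 with an estimated correlation). Fatty acid genes had a median of 0.26 with 1 called, the elongase Elovl2 at 1.02 ± 0.09 (4 higher and 1 lower adjusted over the list alone; adjusted p = 7.10e-06, and 0.0926). For amino acid genes (median 0.18, adjusted p = 0.000368, and 0.335) 3 were higher and 3 lower (7 and 3 adjusted over the list alone), among them Nags at -1.32 ± 0.15, Kynu at 0.75 ± 0.16 and Glul at 0.70 ± 0.11. Acute phase genes had 2 higher, also when adjusted over the list alone, Steap4 at 1.23 ± 0.19 and ceruloplasmin Cp at 0.59 ± 0.09, with adjusted p = 0.000842 (0.272) and a median of 0.0050 that turned negative after median centring (-0.06). Of the CYP list 2 were higher (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.000368, and 0.202), Cyp2u1 and Cyp2c70 (0.91 ± 0.20), with a median of 0.02 that was -0.04 after median centring. In the bile acid list (median 0.15, adjusted p = 0.00988, and 0.202) the 2 called genes went the other way, Abcc3 at -1.03 ± 0.17 and Acox2 at -0.59 ± 0.11 (1 higher and 3 lower adjusted over the list alone). Calls for Cyp2c70, Kynu, Cyp2u1 and Acox2 ended without any 1 of 13, 11, 4 and 3 arrays (0.78 to 1.06, 0.63 to 0.83, 0.998 to 1.387 and -0.62 to -0.51), and those for Cyp2c70 and Kynu also after median centring. In each pair of adjusted p in parentheses the second is with an estimated correlation.

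Of 33 complement and coagulation genes 1 was called, also over the list alone, Cfb at -0.36 ± 0.05 (lost after median centring), while the list's median was 0.07 (adjusted p = 0.000745, and 0.224 with an estimated correlation). Glucose genes had Gckr at -0.96 ± 0.16 and Fbp1 at -0.54 ± 0.09 (2 higher and 2 lower adjusted over the list alone), and their median of 0.05 was -0.02 with scan day as a block and -0.0084 after median centring (adjusted p = 0.0442, 0.0590 with the block, 0.0788 without replicate 6, 0.221 after quantile normalization and 0.386 with an estimated correlation). Limma called no member of 6 further lists. Unfolded protein genes had a median of 0.26 (adjusted p = 7.10e-06), extracellular matrix genes of 0.10 (0.000155), stellate cell markers of 0.31 (0.000756), endothelial markers of 0.29 (0.00141), clock genes of 0.21 (0.0368) and genes of the growth hormone axis of 0.06 (0.0368), with adjusted p from 0.1998 to 0.2020 for all of these with an estimated correlation. In that order, 6, 6, 3, 4, 2 and 1 of their members had an unadjusted p under 0.05, and over the list alone 1 unfolded protein gene was higher and 2 endothelial markers were higher and 1 lower. The clock median was -0.03 with scan day as a block (adjusted p = 0.270) and -0.05 within scan day 2, and the clock call was also lost after quantile normalization (0.102) and without replicate 6 (0.0613). The growth hormone call was lost after quantile normalization (0.178), without replicate 6 (0.0613), without knockout TCDD replicate 1 (0.137) and after median centring (0.0728, median -0.0048).

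By limma 501 probe sets differed, 113 higher and 388 lower, and 191 of them by at least 2-fold. The other 21 lists had at most 4 called members each. The count was 239 with scan day as a block, 213 of them the same probe sets, and 310 within scan day 2 (83 shared), the day that held all 4 groups, with a lone knockout corn oil array assumed to vary like the others. Without replicate 1 of the knockout corn oil group it was 333, and without replicate 6 of the wild type TCDD group 552. Of the 29 named calls 10 passed within day 2 and 21 with the block, and those lost with the block were Gstm3 (adjusted p = 0.0635), Fbp1 (0.0764), Glul (0.0818), Kynu (0.0914), Sult5a1 (0.135), Cyp2u1 (0.173), Cyp1a1 (0.193) and Cyp2c70 (0.245).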

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

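The tests of degraded RNA, of RNA from a wild type liver and of a mislabelled genotype were chosen after the results they bear on were seen. Levels of named genes and measures of array quality were checked for an array far from the rest of its group in the 2 wild type groups, by the ratio of its gap to the nearest array over the range of the group. Of 210 checks 21 passed the limit, and chance alone passes about 1 in 20 groups.

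Replicate 6 of the wild type TCDD group held 10 of these 21, being highest in the gap between 3′ and 5′ control probe sets of Gapdh (ratio 0.973) and Actb (0.645), in residual SD (0.854), in median level (0.662) and in Ndufb3 (0.666), and lowest in Hmox1 (0.913), Fads2 (0.811), Sult5a1 (0.732), Cyp1a2 (0.724) and Cyp1a1 (0.703). A candidate explanation is degraded RNA, since the Gapdh gap was 1.98 on the log2 scale on this array against -0.165 to -0.0112 on the other 16. The hybridisation controls had a mean of 10.7, inside the range of the other arrays (10.5 to 11.1). These values had already been normalized across arrays, which can remove a fault shared by all probe sets. The control mean therefore cannot decide on a fault of hybridisation or scanning. The AHR battery showed no stronger response to TCDD: its 9 called genes averaged 11.10 on this array and 11.04 to 11.18 on the other 5 of its group. Cyp1a1 and Cyp1a2 among them lie near the top of the scale, and the RNA of this array is in doubt. The battery mean therefore does not decide on a stronger response. Whether the RNA was degraded stays open, since the Gapdh gap is itself among the measures that set this array apart.

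Replicate 1 of the knockout TCDD group had Cyp1a1 at 12.64 and Cyp1a2 at 13.27, where the highest other knockout array had 7.18 and 11.69. RNA from a dosed wild type liver would need a share of 14.7% to give that Cyp1a2 level and would lift the 19 genes that rose at least 8-fold in wild type by a median of 1.48, whereas their median lay at -0.000627 above the other knockout TCDD arrays (spread 0.291). A mix-up with a wild type mouse of this series is argued against as well, since 11.6% of 277 genes called by genotype lay nearer to the wild type. Age and source went with genotype in these genes. They therefore cannot tell whether a mouse of the knockout source carried the receptor. The 19 genes above bear on this, since a receptor that responded to TCDD as in wild type would have raised them at least 8-fold. Their median of -0.000627 (spread 0.291) argues against such a response on this array. Activation of the receptor CAR is argued against by its 7 measured targets, which averaged 9.59 on this array and 9.27 to 9.76 on the other knockout arrays. What raised Cyp1a1 and Cyp1a2 there stays open. On this array 8 genes lay more than 1 above every other knockout array, against 3 to 27 such genes on the others. The 8 were Cyp1a1 (5.47), Fmr1nb (2.15), Cyp26a1 (1.82), Gh (1.63), Cyp1a2 (1.58), Dntt (1.26), St6galnac3 (1.12) and Gpx3 (1.02). Of these only Cyp1a1 and Cyp1a2 were called for TCDD in wild type.

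Male-biased liver genes were lower in knockout livers given corn oil (median -0.79). A female among these mice is argued against, since 0 of the 3 arrays had Xist above and Y-linked genes below the wild type range (Xist at most 2.91, Y-linked genes at least 6.49). Scan day as the whole cause is argued against by medians of -0.77 with the block, -0.93 within day 1 and -0.66 within day 2, and by camera with the block and the preset correlation (adjusted p = 2.18e-17), although with an estimated correlation the block moved adjusted p from 0.0178 to 0.0551 and ended that call. A single knockout corn oil array as the cause is argued against too, since the highest adjusted p by camera without each of them in turn was 9.05e-14 with the preset correlation. This test left out no wild type array and was not run with an estimated correlation. Age, source of the mice and genotype remain open and were not separated by the design.

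Other arrays far from their group were spread over genes. In the wild type corn oil group replicate 1 was lowest in Acox2 (0.736), Glul (0.751) and Hsd3b5 (0.751), replicate 4 was lowest in Hamp2 (0.871) and Cyp17a1 (0.833) and highest in Pcp4l1 (0.775), and replicate 3 was lowest in Pmm1 (0.848). In the wild type TCDD group replicate 2 was lowest in Rdh9 (0.721) and highest in Srxn1 (0.666), replicate 3 was highest in Itih3 (0.692) and replicate 4 highest in Mmd2 (0.914).

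The TCDD effect differed between the genotypes by the limma test of the difference itself for 29 named genes (log2, knockout minus wild type). It was higher in the knockout for Serpina7 (5.05), Serpina12 (2.27), Tk1 (1.92), Enho (1.75), Steap4 (1.23), Cyp2u1 (1.19), Elovl2 (1.02), Cyp2c70 (0.91), Kynu (0.75), Glul (0.70) and Cp (0.59). It was lower for Cyp1a1 (-8.00), Pcp4l1 (-6.28), Cyp1b1 (-6.12), Tiparp (-5.38), Fmo2 (-4.90), Acot3 (-4.84), Nqo1 (-4.26), Cbr3 (-3.66), Ahrr (-3.08), Srxn1 (-1.83), Sult5a1 (-1.82), Gstm3 (-1.79), Nags (-1.32), Abcc3 (-1.03), Gckr (-0.96), Acox2 (-0.59), Fbp1 (-0.54) and Cfb (-0.36). Those lost with scan day as a block or without single arrays are named in the report.

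Other divisions of the same arrays into groups of the same sizes gave fewer calls than the real one in 3 of the comparisons. Chance is argued against for TCDD in wild type and for genotype. The divisions took no account of scan day, which was spread unevenly over the groups. For TCDD in wild type 1 of 100 divisions, the real one, gave as many probe sets (1882), and the highest other gave 843, by exchanging the labels of all but 1 dosed array. For genotype 1 of 56 gave as many as 654 (highest other 6), and for the difference of effects 1 of 100 gave as many as 501 (highest other 31). The divisions for the difference of effects exchanged genotype labels within each dose. Differences between the genotypes then enter the spread and lower the counts, so these divisions cannot decide on chance for that comparison. For TCDD in knockout 5 of 10 divisions gave at least 6 probe sets, with 16 as the highest other, and 10 divisions are too few for a share under 0.05.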

How the results depend on the processing

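Fits within a scan day and the scan day block without the array of doubted RNA were chosen after seeing the data. The count for TCDD in wild type (1882) stayed within 1.5 times under both scalings, the filter on level, the trended prior, array weights, both blocks, 1 probe set per gene, only the groups compared and every single array left out (1466 to 1866). It was 456 within scan day 1 and 564 within scan day 2, fits with fewer arrays, and 1070 at an adjusted p under 0.01 and 287 with a difference of at least 2-fold, which are stricter by construction.

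The count of 6 for TCDD in knockout moved under most settings: 3 with median centring, 2 with probe sets above the median level, 51 with array weights, 1 with scan day as a block, 2 with the block and without the array of doubted RNA, 2 with 1 probe set per gene, 255 within scan day 2 (47 higher and 208 lower, where the 6 were all higher), 2 at 2-fold or more, and 1 to 34 without each array in turn. By limma it was 0 with only the groups compared and 0 at an adjusted p under 0.01, against 1263 at an unadjusted p under 0.05. The cause was not tested. The genotype count (654) was 1310 with array weights, 294 within scan day 1, 306 at an adjusted p under 0.01, 172 at 2-fold or more, and 404 to 780 without each array. The count for the difference of effects (501) was 1071 with array weights, 239 with scan day as a block, 310 within scan day 2, 225 with the block and without the array of doubted RNA, 217 at an adjusted p under 0.01, 191 at 2-fold or more, and 333 to 552 without each array. Array weights gave the array of doubted RNA a weight of 0.0487; why they raised these counts was not tested.

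Replicate numbers did not pair the arrays: residuals of arrays with the same number had a median correlation of -0.0620 over 20 pairs, against 0.00944 over 85 other pairs. By scan day the median was 0.0394 over 44 pairs of the same day (-0.263 to 0.425). It was -0.0249 over 61 pairs of different days (-0.339 to 0.210). The highest value was that of knockout TCDD replicate 3 with wild type corn oil replicate 5, the only arrays of day 3. The difference by scan day was not tested. With the replicate block the counts were 1436, 0, 347 and 364 for TCDD in wild type, TCDD in knockout, genotype and the difference of effects.

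The correlation across genes of the TCDD and genotype effects (0.0585) turned to -0.0196 and their covariance (0.00486) to -0.00176 with the controls divided, which removes the shared arrays by construction, and without each array the correlation was 0.0503 to 0.0970. Among named genes no difference that passed in either fit changed direction, while some that passed in neither did, such as Cyp1a1 for TCDD in knockout (-1.18 to 2.48 without each array). Over all settings 484 values lost the call, 3 gained it and 3615 kept their side of the threshold. The replicate block ended 31 named calls, and the scan day block and the fit of only the groups compared ended 19 each. Of the lists described by their test, an estimated correlation ended 46 calls, array weights 17, the replicate block 12, leaving out wild type TCDD replicate 6 11, and quantile normalization, median centring and the scan day block 7 each. The PPARA list for TCDD in knockout changed direction with array weights (adjusted p = 0.869), and the cause was not tested. The 17 ended by array weights were, for TCDD in wild type, the bile acid, clock, complement, glucose, growth hormone, male-biased, hepatocyte and stellate cell lists, for TCDD in knockout the male- and female-biased lists, for genotype the CYP and bile acid lists, and for the difference of effects the bile acid, clock, complement, female-biased and glucose lists. Genes near the lowest values of an array have little signal over background, so their differences are limited from below.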

Other observations

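Some gene groups outside the lists described held calls; the genes here were chosen after their values were seen. With TCDD in wild type, 5 of 35 genes of PPARA and fatty acid oxidation rose and 1 fell (13 at an unadjusted p under 0.05), while the list as a whole did not pass (adjusted p = 0.879). Acyl-CoA thioesterases release free fatty acids from coenzyme A, and 4 picked from that list rose: Acot3 by 3.71 ± 0.50 (SE, log2), Acot4 by 1.97 ± 0.35, Acot1 by 1.91 ± 0.18 and Acot2 by 0.76 ± 0.14. In the knockout Acot1 differed by 0.03 ± 0.25, Acot4 by -0.87 ± 0.47 and Acot3 by -1.12 ± 0.68, and the difference between the genotypes was -1.88 ± 0.31 for Acot1, -2.84 ± 0.59 for Acot4 and -4.84 ± 0.84 for Acot3. Those of Acot1 and Acot4 did not pass with scan day as a block (adjusted p = 0.0864 and 0.0592), and that of Acot4 was also lost without any 1 of 10 arrays (-3.06 to -2.49). The baselines differed: by group means with corn oil, the knockout read 5.70 against 3.35 in wild type for Acot3 and 6.50 against 5.23 for Acot4. For Acot1 these means were 9.42 and 9.53. The wild type level of Acot3 lay near the array medians (3.08 to 3.19). Acot2 read 6.91 with corn oil and 6.63 with TCDD in the knockout. The peroxisomal fatty acid transporter Abcd2 rose by 2.42 ± 0.47, from 4.38 to 6.80. In the knockout its mean was 6.80 with corn oil and 6.68 with TCDD. The interferon-induced protease gene Usp18 rose by 2.17 ± 0.26, with a difference between the genotypes of -2.91 ± 0.43. Of 26 interferon response genes 3 were called with TCDD in wild type, Usp18 among them.

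By genotype in livers given corn oil, 2 of 28 glucose and glycogen genes were higher and 4 lower, and the list did not pass (adjusted p = 0.665). Pyruvate kinase Pklr was lower by 1.78 ± 0.19, the glucose transporter Slc2a2 by 1.28 ± 0.21 and glycogen phosphorylase Pygl by 0.68 ± 0.11, and the transaminase Got1 was higher by 2.46 ± 0.34. The methyltransferase Nnmt was higher by 2.74 ± 0.29, the growth arrest gene Btg2 by 2.71 ± 0.31 and Cd36 by 1.58 ± 0.23. Malic enzyme Me1 was lower by 0.95 ± 0.09. These 8 were picked among the calls kept without each array in turn. Without any 1 of 11 arrays the call for Gbe1, another of the 4 lower glucose genes, was lost (-1.07 to -0.86), that for Lyve1 without any 1 of 14 (1.32 to 2.19), those for Slc40a1, Slc11a2, Sult1a1 and Lepr without either of 2, and that for Fbp1 without replicate 1 of the knockout corn oil group. With scan day as a block the calls for Lyve1 (adjusted p = 0.102), Slc40a1 (0.0503) and Slc11a2 (0.0593) were lost.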
